A study of Mus musculus with 66 samples.

How the data were processed

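Hippocampal poly(A) RNA of C57BL/6 mice was sequenced in 66 libraries, 1 per sample label. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy kit and libraries were made with NEBNext poly(A) isolation and random priming. Per the submitters' processing notes, STAR, Picard and edgeR were used with the build GRCm38. Versions, the annotation, the counting rule and the use of strand are not given in the sources used here. The labels do not say that each library is a separate animal, so p-values measure the spread between these libraries.

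The deposited values are a signal per gene, 1 table per cohort: reads-per-million divided by 1 scaling factor per library. Within each library they are whole multiples of the value of 1 read, and dividing by that step gave whole reads for 100% of values at a tolerance of 0.01 reads (largest deviation 1.41e-04 reads). The recovered totals were 42462638 to 65907005 reads per library. The deposited factors ran from 0.957 to 1.04. In the 12-month table they equal the TMM factors (trimmed mean of M values) computed from the recovered reads, within 9.21e-10%, and in the 3-month table they differ from such factors by up to 1.21%. The tables hold 55421 genes each, with 120 extra entries for repeated symbols, 27 symbols turned into dates by a spreadsheet and 12 genes named by Ensembl ID, and 96.2% of symbols match GENCODE vM21, from which coordinates and gene types on GRCm38 were taken. All library columns matched 1 label. No pair of libraries in a group agreed within sampling noise (smallest chi-square per degree of freedom 5.77), so none was treated as a duplicate.

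Groups were taken from the labels: cohort, extract and time post injection. For each cohort, limma-trend was fitted to log2(deposited value + 1) with 1 mean per group and a spread shared over the 6 groups, after edgeR's filterByExpr on recovered reads, leaving 19976 genes in the 3-month cohort and 20084 in the 12-month cohort. A fold change on this scale understates the change of low genes. The plan assumed raw counts and edgeR's quasi-likelihood test, with limma-trend as the fallback for other values. Because the deposited values are not counts, the fallback was used, and the quasi-likelihood test on recovered reads was added as an alternative after seeing the data. The plan's relative-log-expression and upper-quartile scalings and its robust spread were applied to limma. The joint comparisons of both cohorts had been planned only if both tables held raw counts on the same genes. This was met only through the recovered reads, which were scaled together with TMM and fitted as above over all 12 groups (21297 genes). An alternative that keeps each table as deposited was added. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05.

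The AD contrast was the equal-weight mean of the AD minus Ctrl differences at 1, 3 and 5 mpi, also taken at each time. The other contrasts were 5 minus 1 mpi of the AD effect and of Ctrl libraries, 12 minus 3 months of the AD effect, and 12 minus 3 months of Ctrl libraries. The 39 gene lists, of cell types, regions and pathways, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Members were also adjusted over the list alone. The contrasts, lists and rule for named genes were chosen before the data were examined. By that rule the genes named in a main comparison were the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 value of at least 1, leaving out gene models, and 3 each way elsewhere. Where fewer passed, the genes with the smallest p-values up to 5 were given as values that did not pass. Up to 4 members of each list and 12 fixed genes were also available, and examples of lists are given beyond these where the text counts them. Called genes outside the rule are said to be so.

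Settings planned as alternatives were other scalings, DESeq2 on recovered reads, no filter, a stricter filter, each library left out in turn, a replicate block, only the compared groups in the fit, robust spread, and covariates for choroid plexus genes, sex-linked genes or 1 surrogate variable. Added after seeing the data were the quasi-likelihood test, a pseudocount of 0.1, covariates for choroid plexus and sex-linked genes together or for myelin genes, leaving out the 4 libraries of 1 mpi with the highest Inhba in the 3-month cohort, and leaving out 2 libraries of the 12-month cohort with low Xist beside Y-linked genes. Other splits of the same libraries were drawn 100 times at most. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0 were used.

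The limma step was tested on simulated counts drawn from the real means and library sizes, with independent genes. Changed genes were drawn only from those with a log2 mean level of at least 1. Many were changed at once, which eases the adjustment compared with real contrasts that call few genes. False calls numbered 10 of 219 in the 12-month AD contrast and 15 of 224 in the 3-month AD contrast. Of 100 genes changed by 1.5-fold it recovered 93% in the 12-month AD contrast (20084 genes) and 94% in the 3-month AD contrast (19976 genes). It recovered 81% and 85% for 5 against 1 mpi in 3-month and 12-month Ctrl libraries, 84% for AD at 5 mpi in the 12-month cohort, 74% for the same in the 3-month cohort, 89% for the difference of AD effects between ages and 94% for age in Ctrl libraries (21297 genes each for the last 2). Of 100 genes changed 2-fold it recovered 96%, 99%, 92%, 97%, 93%, 90%, 93% and 100% in the same order. Differences in dissection and cell composition between animals are not part of this simulation.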

Results

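The series measured poly(A) RNA from the hippocampus of C57BL/6 mice, a common inbred laboratory strain, after injection of brain extract. The extract came from Alzheimer's disease brain (AD) or from control brain (Ctrl). The series title names seeded tauopathy, in which aggregated tau from an injected extract templates the aggregation of the host's own tau. Mice are labelled 3 or 12 months of age and were collected 1, 3 or 5 months post injection (mpi). The labels do not say whether the age was that at injection or at collection. The 66 libraries form 12 groups, 29 libraries in the 3-month cohort and 37 in the 12-month cohort. In the 3-month cohort, Ctrl and AD groups held 5 and 6 libraries at 1 mpi, 5 and 5 at 3 mpi, and 5 and 3 at 5 mpi. In the 12-month cohort they held 5 and 6, 6 and 6, and 7 and 7. Depth ran from 42462638 to 65907005 reads assigned to genes per library. Levels below are the deposited scaled reads-per-million values. Libraries with high Xist, transcribed from the inactive X chromosome, and libraries with high Ddx3y, a Y-linked gene, occurred in every group, so both sexes were present throughout, but not in equal shares.

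The first question was which hippocampal genes differ after AD extract in the older mice. Averaged over the 3 time points of the 12-month cohort, C3, the central component of the complement cascade, rose by a log2 fold change of 0.95 (SE 0.17), from 12.2 ± 5.60 (SD, n = 18) in Ctrl to 26.9 ± 17.3 (SD, n = 19) in AD libraries. Of the 19 AD libraries, 18 lay above the Ctrl mean of their own time point. Pcsk6, a proprotein convertase that cleaves secreted precursors, rose by 0.24 (SE 0.045), from 23.1 ± 1.75 (n = 18) to 27.7 ± 3.28 (n = 19), also in 18 of 19 AD libraries. These were the 2 genes of 20084 tested that passed (limma, adjusted p = 0.0360 for both). C3 lies on chromosome 17 at 57203970 to 57228136 and Pcsk6 on chromosome 7 at 65861734 to 66050386 (GRCm38), both protein-coding. The genes that followed did not pass. Trem2, a lipid-sensing receptor of microglia, had a log2 fold change of 0.29 (20.3 ± 4.13 in AD against 16.2 ± 2.50 in Ctrl). The value was 0.62 for Cst7, a cysteine protease inhibitor induced in activated microglia, 0.33 for Ctsd, a lysosomal aspartyl protease, and 0.45 for Tlr2, a receptor for microbial lipopeptides (adjusted p = 0.0802 for each of the 4). At an unadjusted p under 0.05, 3075 genes passed where 1004.2 would by chance. The quasi-likelihood test of edgeR on recovered reads called 2 genes and DESeq2 called 163, 138 higher and 25 lower. Both limma calls ended when any 1 of 20 of the 37 libraries was left out, though the log2 fold changes stayed between 0.89 and 1.03 for C3 and between 0.23 and 0.26 for Pcsk6 (adjusted p up to 0.0904). They also ended with covariates. For choroid plexus genes C3 gave 0.82 (SE 0.16) and Pcsk6 0.25 (SE 0.047; adjusted p = 0.0831 for both), and for a surrogate variable 0.78 (SE 0.16) and 0.24 (SE 0.048; adjusted p = 0.145). Both values shrank with a covariate for myelin genes, to 0.60 (SE 0.18) and 0.14 (SE 0.044; adjusted p = 0.940). The count was 66 without AD library 1 of 5 mpi. Among genes named in advance, Gfap, the intermediate filament of astrocytes, had a log2 fold change of 0.24 (higher in 17 of 19 AD libraries), Clec7a, a microglial pattern receptor, 0.59 (14 of 19), and Serpina3n, a serine protease inhibitor of reactive astrocytes, 0.27 (16 of 19; adjusted p = 0.110 for each of the 3). C4b, a complement component, stood at 0.42 (16 of 19; adjusted p = 0.104) and Itgax, which encodes the integrin CD11c, at 0.54 (16 of 19; adjusted p = 0.108). Apoe, the main brain apolipoprotein, had 0.15 (18 of 19; adjusted p = 0.156), Cd68, of phagocyte lysosomes, 0.24 (14 of 19; adjusted p = 0.174), and Aif1, a microglial calcium-binding protein, 0.15 (14 of 19; adjusted p = 0.312). Mapt, which encodes tau, had a log2 fold change of -0.04 (462 ± 24.3 in AD against 476 ± 28.5 in Ctrl, adjusted p = 0.452) and App, the amyloid precursor protein gene, -0.03 (adjusted p = 0.557).

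**Figure D1:**
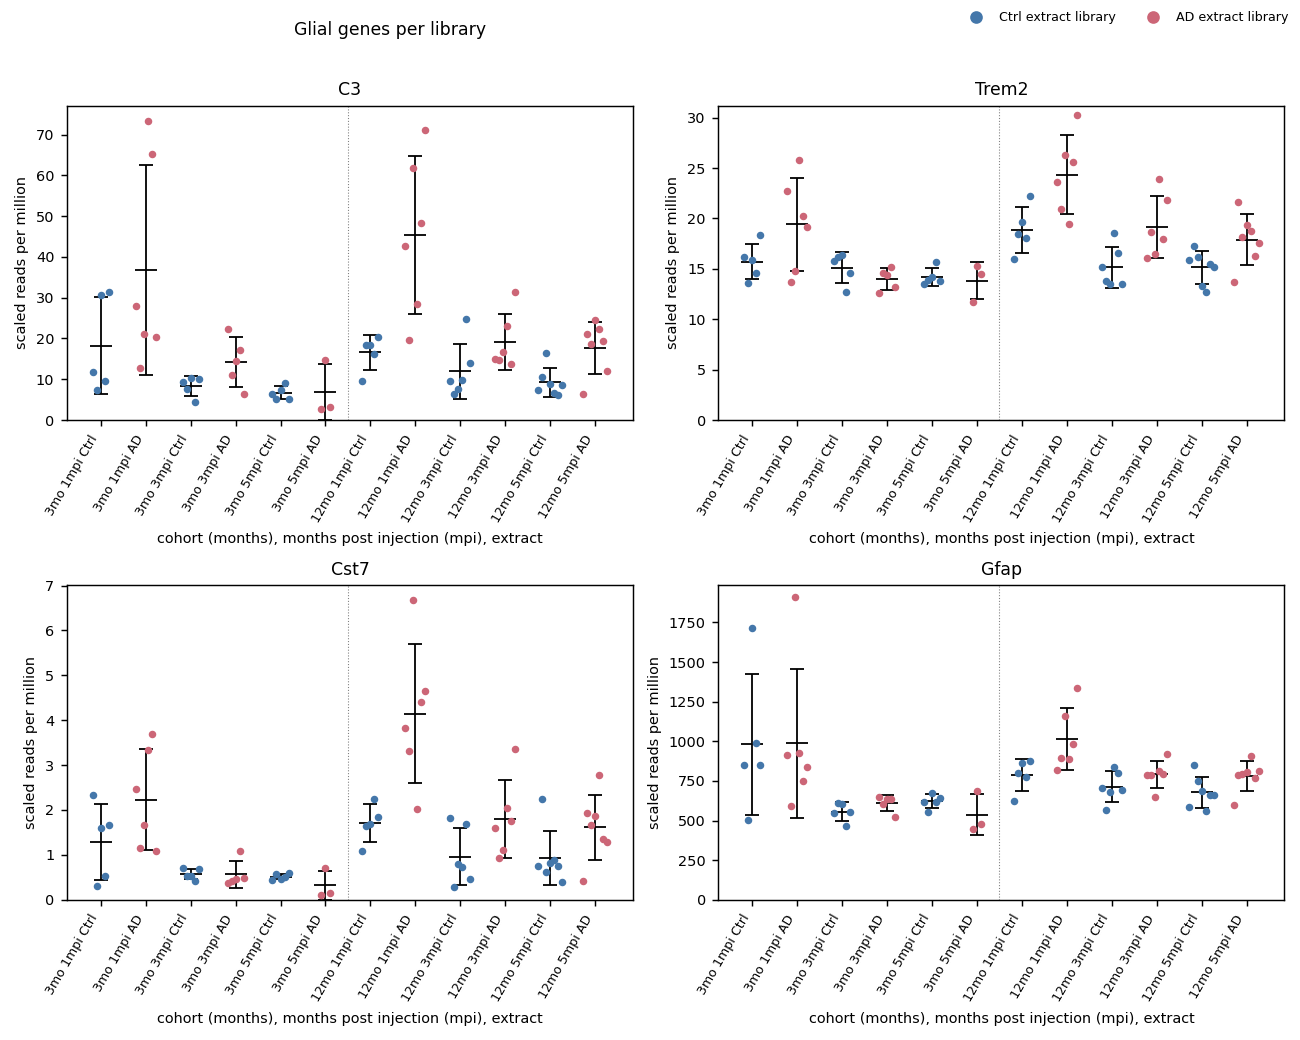
Level of C3, Trem2, Cst7 and Gfap in each library (y axis, scaled reads-per-million) by cohort, time and extract (x axis). Each point is 1 library, and black bars give the group mean ± SD. The highest AD means were at 1 mpi of the 12-month cohort for C3 (45.4 against 16.6 in Ctrl) and Cst7 (4.15 against 1.70).

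Fixed gene lists were tested in the same contrast. The list of disease-associated microglia genes, those induced when microglia respond to amyloid or dying neurons, was higher in AD: 24 of its 27 members had a positive log2 fold change, with a mean of 0.25. Over all genes 0 members passed, and 20 higher and 1 lower passed when adjusted over the list alone. The members that rose by that count included Trem2, Cst7, Gpnmb (0.51), Lgals3 (0.49) and Tyrobp (0.24), and the one that fell was Ank (-0.06), a pyrophosphate transporter. All 20 genes of myelin and mature oligodendrocytes were positive (mean 0.19; 0 over all genes, 16 adjusted over the list alone), among them Trf, which encodes transferrin (0.38), Klk6, a myelin-associated protease (0.51), and Mbp, myelin basic protein (0.17). Of 27 reactive astrocyte genes 25 were positive (mean 0.21; 1 over all genes, 12 adjusted over the list alone), including Steap4 (0.65), Lcn2, which encodes lipocalin 2 (0.76), and Vim, which encodes vimentin (0.26). The complement list gave 1 member over all genes and 6 adjusted over the list alone, with C1qa (0.30), C1qb (0.24) and C1qc (0.25), the 3 chains of C1q, beside C3 and C4b. The lysosome and autophagy list gave 0 over all genes and 14 of 25 adjusted over the list alone, such as Hexa (0.16) and Lamp1 (0.10). Homeostatic microglia genes gave 0 and 6 of 16 on the same 2 counts, cytokine and NF-kB genes 0 and 3 of 19, and genes of ciliated ependymal cells 0 and 7 of 8, with Foxj1, the regulator of motile cilia, at 0.41. The synapse list moved the other way: 0 of its 25 members were positive, the mean was -0.07, and 14 were lower when adjusted over the list alone against 0 over all genes, among them Syn1 (-0.11), Syn2 (-0.10) and Snap25 (-0.09) of the presynaptic release machinery.

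Of the 39 lists, 16 were called by limma's camera with a preset correlation of 0.01, including each list named so far (adjusted p = 1.26e-15 for disease-associated microglia and 3.63e-10 for synapse). With an estimated correlation none was called, and the smallest adjusted p = 0.162 was shared by those lists. By fry, whose p tests whether the genes of a list move on balance in 1 direction, 9 lists passed, 8 higher and 1 lower. They were disease-associated microglia (adjusted p = 0.0115), myelin (0.0168), lysosome (0.0168), reactive astrocyte (0.0221), homeostatic microglia (0.0221), synapse (0.0221), cytokines (0.0247), ependymal (0.0297) and complement (0.0340). Interferon response genes were positive in 28 of 28 members (mean 0.28; 0 over all genes, 10 adjusted over the list alone, such as Cxcl10 at 0.57 and Rsad2 at 0.37), with adjusted p = 0.257 with an estimated correlation and 0.0783 by fry. Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were higher in the same AD libraries (17 of 17 positive, mean 0.79; 0 members passed on either count, whether over all genes or adjusted over the list alone; adjusted p = 0.472 with an estimated correlation, 0.244 by fry). Choroid plexus, ependymal and myelin genes were thus higher in the same AD libraries as the glial lists. No list differed in sign between its median, its mean and its test in this contrast.

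**Figure D2:**
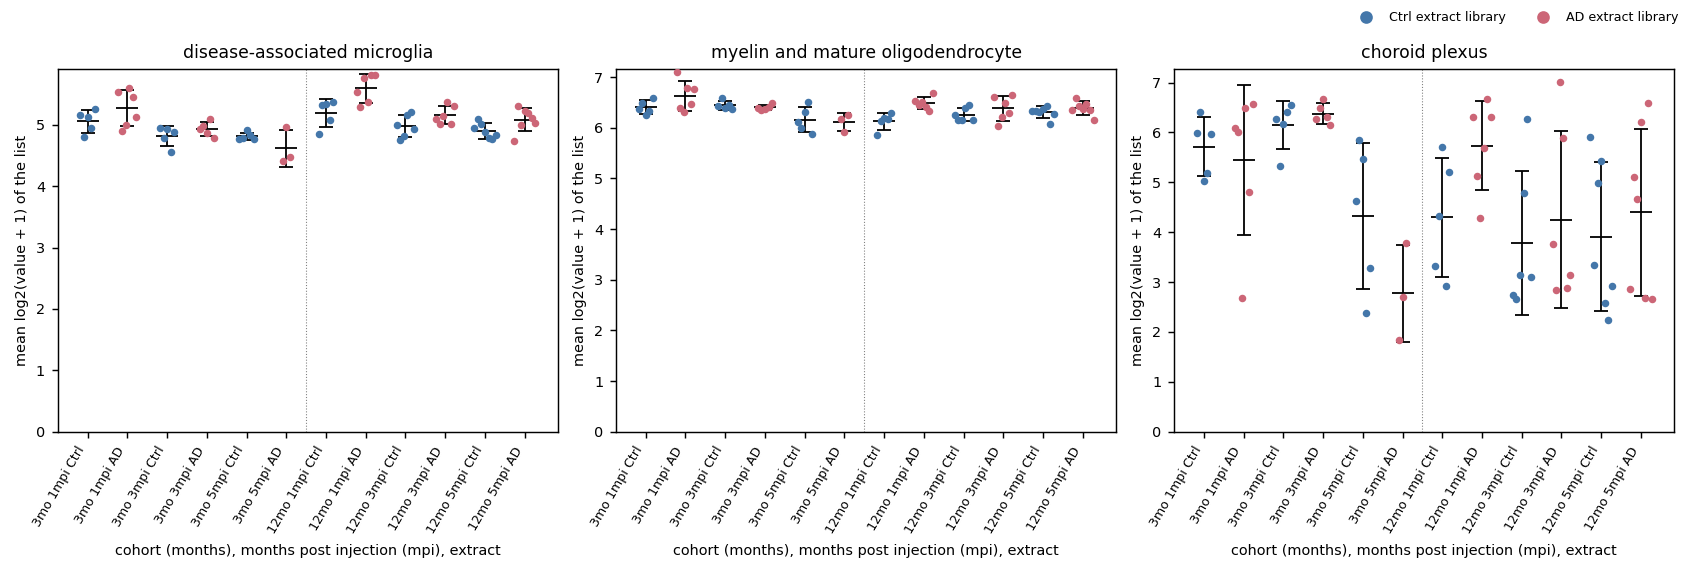
Mean log2(value + 1) over the members of 3 gene lists in each library (y axis) by cohort, time and extract (x axis). Points are libraries and black bars the group mean ± SD. The disease-associated microglia score averaged 5.60 in AD and 5.19 in Ctrl at 1 mpi of the 12-month cohort, while the choroid plexus score spread over several log2 units within most groups.

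Each time point of the 12-month cohort was then taken alone. At 1 mpi, Tgm1, a transglutaminase counted among reactive astrocyte genes, rose by 0.83 (SE 0.15), from 0.313 ± 0.0827 (n = 5) to 1.38 ± 0.558 (n = 6) and higher in 6 of 6 AD libraries, the 1 gene that passed (limma, adjusted p = 0.0343). It falls below the level set for naming genes and was named after its values were seen. C3 had its highest AD level here, 45.4 ± 19.4 (n = 6) against 16.6 ± 4.20 (n = 5), with a log2 fold change of 1.32 that did not pass (adjusted p = 0.147). Dbi, a binding protein for acyl-CoA esters (0.34), Ccdc190 (0.42) and the histone gene H2bc4 (0.45) followed Tgm1 (adjusted p = 0.0969 for each). The disease-associated microglia list averaged 0.40 at 1 mpi (fry adjusted p = 0.0122, and adjusted p = 0.0781 with an estimated correlation; 0 over all genes, 17 adjusted over the list alone), the myelin list 0.36 (fry adjusted p = 0.0122, estimated correlation adjusted p = 0.0781; 0 over all genes, 20 of 20 adjusted over the list alone), and the choroid plexus list 1.43 (fry adjusted p = 0.25). At an unadjusted p under 0.05, 2427 genes passed at 1 mpi. DESeq2 called 42 genes and the edgeR test 0, and the Tgm1 call ended when any 1 of 9 of the 11 libraries was left out.

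At 3 mpi of the 12-month cohort no gene passed in limma, with 796 at an unadjusted p under 0.05 against 1004.2 expected, and 0 by edgeR and by DESeq2. Under the naming rule the smallest p-values belonged to Wnt16, a secreted Wnt ligand (log2 fold change -0.58), and Pdzph1 (0.38; adjusted p = 0.995 for both), and C3 stood at 19.1 ± 6.92 (n = 6) in AD against 12.0 ± 6.77 (n = 6) in Ctrl. At 5 mpi 11 genes rose and 0 fell. Of the 11, 10 are annotated as processed pseudogenes, which are reverse-transcribed copies of other genes' messages. Under the naming rule these were Vcp-rs (0.52, 4.11 ± 0.988 in AD against 2.52 ± 0.247 in Ctrl, n = 7 each), Morf4l1-ps1 (0.42) and Rpl14-ps1 (0.40). The others, named after their values were seen, were Gm11808 (0.74), which is annotated as protein-coding, Gm12715 (0.60), Gm13456 (0.57), Rpl34-ps1 (0.44), Gm13910 (0.39), Gm1821 (0.38), Apoo-ps (0.37) and Gm10819 (0.36). Each was above the Ctrl mean in 7 of 7 AD libraries. Limma gave adjusted p-values from 0.00167 for Gm13456 to 0.0454 for Morf4l1-ps1 and Gm13910. Reads of a pseudogene and its parent can be hard to tell apart, so these levels are uncertain. The 5 parents that the symbols name had log2 fold changes with a median of -0.05 (Vcp -0.05, Morf4l1 -0.09, Rpl14 -0.06, Rpl34 0.03, Apoo 0.0055). C3 had a log2 fold change of 0.84 at 5 mpi and did not pass (adjusted p = 0.376). At this time 1705 genes had an unadjusted p under 0.05, edgeR called 13 genes and DESeq2 27. With only the 5 mpi libraries in the fit no gene passed, and the count ran from 6 to 23 as single libraries were left out.

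Whether the AD effect changed over time in the 12-month cohort was tested as the effect at 5 mpi minus that at 1 mpi. Gm1821, a transcribed processed pseudogene on chromosome 14 at 46084028 to 46085000, was the 1 gene that passed, with a difference of 0.52 (SE 0.092, limma adjusted p = 0.0444), and was named after its values were seen. Its level was 28.6 ± 3.07 (n = 7) in AD and 21.7 ± 2.00 (n = 7) in Ctrl at 5 mpi, with 7 of 7 AD libraries above the Ctrl mean there and 0 of 6 at 1 mpi. C3 had a difference of -0.48 (SE 0.41, adjusted p = 0.933). At an unadjusted p under 0.05, 1171 genes passed, DESeq2 called 5 and edgeR 3. The Gm1821 call ended without any 1 of 17 of the 25 libraries.

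In the 3-month cohort the same AD contrast gave no gene past the threshold. Averaged over times, the smallest p-values under the naming rule belonged to Syk, a kinase downstream of immune receptors (log2 fold change 0.24, SE 0.053; 5.94 ± 0.807 in AD, n = 14, against 4.85 ± 0.801 in Ctrl, n = 15), Inmt, an indolethylamine methyltransferase (-0.37), and Ppcdc, an enzyme of coenzyme A synthesis (0.13; adjusted p = 0.979 for each). C3 had a log2 fold change of 0.44 (SE 0.27; 22.3 ± 21.2 against 11.1 ± 8.40; higher than the time-matched Ctrl mean in 10 of 14 AD libraries). The other genes given in every AD contrast were C4b 0.21 (11 of 14), Clec7a 0.21, Serpina3n 0.15, Itgax 0.12, Cst7 0.09, Aif1 0.07, Apoe 0.05 (10 of 14), Trem2 0.04, Cd68 0.04, Mapt 0.03 (7 of 14), App -0.0031 and Gfap -0.03 (6 of 14), each with an adjusted p = 1.00. Limma called 0 of 19976 genes, 790 had an unadjusted p under 0.05 where 998.8 would by chance, edgeR called 0 and DESeq2 5. The widest of these intervals were those of C3, from -0.11 to 0.99, and Clec7a, from -0.12 to 0.55.

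Among the lists, all 16 glucocorticoid response genes, which corticosterone induces, were positive in the 3-month cohort, with a mean of 0.31. Over all genes 0 passed, and 7 adjusted over the list alone, including the metallothionein gene Mt2 (0.38), Tsc22d3 (0.33) and Fkbp5 (0.27), a regulator of the glucocorticoid receptor. This rests largely on AD library 2 of 5 mpi, with a list score of 6.20 against 4.68 ± 0.0997 (n = 5) in Ctrl, and next on AD libraries 1, 2 and 3 of 3 mpi, at 5.73, 5.28 and 5.41 against 4.86 ± 0.0893 (n = 5). At 1 mpi the score was 4.72 in AD and 4.66 in Ctrl. Without AD library 2 of 5 mpi the mean was 0.14, 14 of 16 members were positive and 0 passed on either count, over all genes or adjusted over the list alone. Camera with the preset correlation called 11 of 39 lists, 7 higher and 4 lower. With an estimated correlation it called 0 (adjusted p = 0.391 for glucocorticoid response, the smallest), and fry called 0 lists (adjusted p = 0.610 for the same list). The disease-associated microglia list averaged 0.04, and -0.016 to 0.078 without single libraries, the lowest without AD library 2 of 5 mpi. This mean joins opposite directions. The score was 5.27 in AD and 5.06 in Ctrl at 1 mpi, and 4.93 and 4.82 at 3 mpi. At 5 mpi it was 4.62 ± 0.306 (n = 3) in AD and 4.81 ± 0.0594 (n = 5) in Ctrl. The choroid plexus list averaged -0.53 (17 of 17 negative; adjusted p = 0.859 with an estimated correlation), or -0.34 without AD library 3 of 1 mpi.

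At single time points of the 3-month cohort no gene passed either (limma). At 1 mpi, Csf1, a growth factor for microglia (0.29), Cyth4 (0.38), Dock1 (0.22) and Pam (-0.21), a peptide-amidating enzyme, had the smallest p-values under the naming rule (adjusted p = 0.796 for each). At 3 mpi the smallest belonged to mt-Atp8, a mitochondrially encoded subunit of ATP synthase (0.70, adjusted p = 0.438), and at 5 mpi, leaving out gene models, to Inmt (-0.90, 1.15 ± 0.0774, n = 3, against 3.04 ± 0.391, n = 5; adjusted p = 0.157) and Lars2, a mitochondrial leucyl-tRNA synthetase (-0.77, adjusted p = 0.527). Lars2 moved with the gene model Gm42418, a sign of ribosomal RNA carry-over, which had the smallest p-value of all (509 ± 95.7, n = 3, against 1216 ± 444, n = 5; adjusted p = 0.157). Unadjusted p-values under 0.05 numbered 1006, 910 and 922 at 1, 3 and 5 mpi, DESeq2 called 2, 1 and 7 genes, and edgeR called 0 at each. The AD effect at 5 mpi minus that at 1 mpi gave 0 genes by limma, edgeR and DESeq2 and 813 at an unadjusted p under 0.05. Csf1 (-0.51), Lhfpl2 (-0.55) and Dock1 (-0.38) led it (adjusted p = 0.648 for each).

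Whether the AD effect differed with age was tested directly in a joint fit. No gene passed for the mean over times: the difference, 12 months minus 3 months, was 0.53 (SE 0.19) for Cst7, 0.26 (SE 0.095) for Trem2 and 0.51 (SE 0.32) for C3, with adjusted p-values of 0.866, 0.866 and 0.889. The smallest p-values under the naming rule belonged to Tspan6 (0.18), Inmt (0.63), Eif2ak2, the interferon-induced kinase PKR (0.41), Slc16a1, a monocarboxylate transporter (0.25), and Prkd3 (0.18; adjusted p = 0.866 for each). Limma called 0 of 21297 genes, 1175 had an unadjusted p under 0.05 against 1064.9 expected, and edgeR called 0 and DESeq2 3. At 1, 3 and 5 mpi alone limma called 0 genes each, with 1164, 717 and 1170 at an unadjusted p under 0.05, edgeR called 0 each and DESeq2 0, 1 and 10. Pcdhga9 (-0.63, adjusted p = 0.782), Uqcrh (-0.27, adjusted p = 1.00) and Inmt (1.21, adjusted p = 0.572) are examples of genes with small p-values at 1, 3 and 5 mpi. The disease-associated microglia list differed by a mean of 0.21 (0 over all genes, 2 adjusted over the list alone), with adjusted p = 0.376 with an estimated correlation and 0.332 by fry. Calls in the 12-month cohort are therefore not shown to be specific to it. Across 19610 genes tested in both cohorts, 55.9% of AD fold changes had the same sign (95% exact binomial interval over genes 55.2 to 56.6). Across these genes, which are not independent replicates, r = 0.03 and the covariance was 1.93e-04. With a surrogate variable in the model the share was 49.95%. The cohorts share no libraries.

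**Figure D3:**
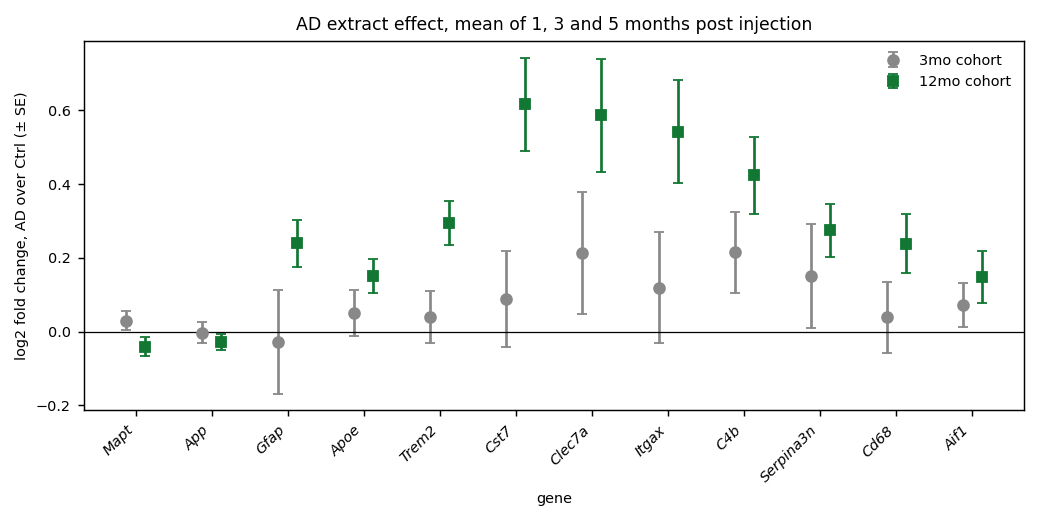
Log2 fold change of AD over Ctrl, averaged over 1, 3 and 5 mpi (y axis), for the 12 genes given in every AD contrast (x axis), in the 3-month cohort (grey circles) and the 12-month cohort (green squares). Bars are ± SE. Cst7 stood at 0.62 in the 12-month cohort and 0.09 in the 3-month cohort, and none of the values shown passed the test.

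Time after injection, over which the mice also aged, was compared within Ctrl mice. In the 3-month cohort 1836 genes differed between 1 and 5 mpi, 1025 higher and 811 lower at 5 mpi (limma, n = 5 each). Of 15 clock genes 7 rose and 1 fell (adjusted p = 0.282 with an estimated correlation for the list). Dbp, a clock output transcription factor, rose by 1.46 (SE 0.20; 52.5 ± 4.57 against 19.9 ± 8.62, adjusted p = 1.33e-04), Ciart by 0.99, Nr1d1, which encodes REV-ERB alpha, by 0.84 and Cry2, a clock repressor, by 0.35. Genes of adult neurogenesis fell: Igfbpl1 to 0.688 ± 0.210 from 4.65 ± 2.39 (log2 fold change -1.65, SE 0.22, adjusted p = 1.33e-04), and the proliferation genes Mki67 (-0.81) and Top2a (-0.83) and the axon guidance gene Draxin (-0.72). Other genes with the largest rises were Slc22a6, an organic anion transporter on the meningeal fibroblast list (1.82), Rtl3 (1.44), Omd, a matrix proteoglycan (1.23), the dentate granule neuron genes Plk5 (1.2), Tdo2, a tryptophan dioxygenase (1.15), and Dsp, which encodes desmoplakin (1.08), Crabp2 (1.13), Pla2g4e (1.13) and Ranbp3l (1.06). In these libraries the meningeal fibroblast score averaged 5.09 ± 0.167 at 5 mpi and 4.49 ± 0.690 at 1 mpi. The score of the whole dentate granule neuron list averaged 5.09 ± 0.185 at 5 mpi and 4.70 ± 0.376 at 1 mpi, where Ctrl library 5 was lowest at 4.13. The largest falls included Prlr, the prolactin receptor and a member of the choroid plexus list (-1.87), Inhba, the activin A subunit gene (-1.60; 9.21 ± 1.35 against 44.2 ± 41.6), Bmp3 (-1.57), Steap4 (-1.14), Nptx2, an activity-regulated pentraxin (-1.13), and Acvr1c, an activin receptor (-1.09). Inhba stood at 95.1 and 84.1 in Ctrl libraries 1 and 3 of 1 mpi and between 12.8 and 15.1 in the other 3. EdgeR called 1792 genes and DESeq2 2476, while upper-quartile scaling gave 577 higher and 842 lower in place of 1025 and 811. The count was lower by over 1.5 times without Ctrl library 1 (997) or 3 (975) of 1 mpi or Ctrl library 3 (1153), 4 (1094) or 5 (933) of 5 mpi, without the 4 libraries of 1 mpi with the highest Inhba (880, chosen after seeing the data), and with only the groups compared in the fit (895).

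In that contrast the adult neurogenesis list had 7 of 13 members lower over all genes and 8 adjusted over the list alone, and was the 1 list still called with an estimated correlation (adjusted p = 0.0132; fry 2.07e-06). The circadian clock list had 7 higher and 1 lower of 15 over all genes and 8 and 1 adjusted over the list alone (fry adjusted p = 6.82e-04; adjusted p = 0.282 with an estimated correlation). Cytosolic ribosomal protein genes rose in 41 and fell in 1 of 84 over all genes, and in 63 and 1 adjusted over the list alone, with Rps21 at 0.37 and Rpl11 at 0.24 (fry adjusted p = 7.06e-04; adjusted p = 0.282 with an estimated correlation). Oxidative phosphorylation genes gave 5 higher of 27 over all genes and 10 adjusted over the list alone (fry adjusted p = 0.0445; adjusted p = 0.685 with an estimated correlation), and inhibitory neuron genes 5 of 16 and 7 (fry adjusted p = 0.0466; adjusted p = 0.685 with an estimated correlation). Chaperone and unfolded protein response genes gave 12 lower and 1 higher of 25 over all genes, and 14 and 1 adjusted over the list alone, with Hspa5, the endoplasmic reticulum chaperone BiP, at -0.80 (adjusted p = 0.685 with an estimated correlation; fry 0.1). Of 20 myelin genes 5 fell over all genes and 6 adjusted over the list alone, with Ugt8a at -0.65 and Mobp at -0.56 (adjusted p = 0.7 with an estimated correlation; fry 0.164). The choroid plexus list averaged -1.40 with 17 of 17 negative and 1 lower on either count, over all genes or adjusted over the list alone (adjusted p = 0.685 with an estimated correlation; fry 0.163), or -0.91 without Ctrl library 4 of 5 mpi. It differed in the same libraries as these lists, and whether the lists depend on it was not tested.

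**Figure D4:**
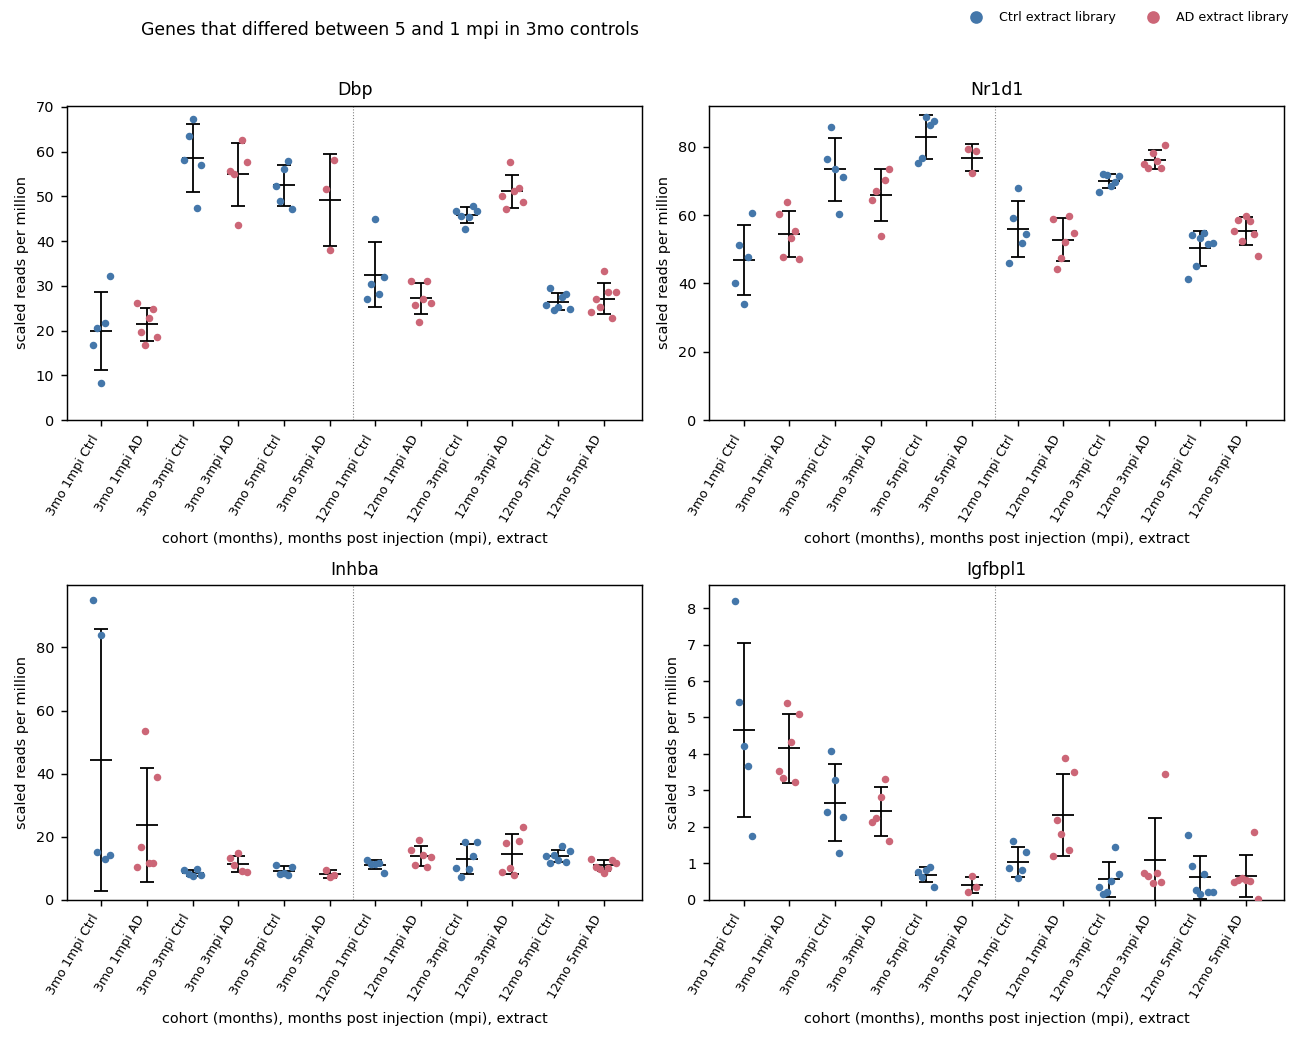
Level of Dbp, Nr1d1, Inhba and Igfbpl1 in each library (y axis, scaled reads-per-million) by cohort, time and extract (x axis), with points for libraries and black bars for the group mean ± SD. In 3-month Ctrl libraries Dbp averaged 19.9 at 1 mpi and 52.5 at 5 mpi, and Igfbpl1 4.65 and 0.688.

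In the 12-month cohort the same Ctrl comparison called 5 genes (limma, n = 7 at 5 mpi against 5 at 1 mpi). Rpl14-ps1 fell by 0.44, from 2.12 ± 0.345 to 1.29 ± 0.131 (adjusted p = 0.0415). The other 4 were named after their values were seen: the processed pseudogenes Gm6180 (-0.91, SE 0.16), Rpl34-ps1 (-0.58) and Gm13456 (-0.51) fell, and the long noncoding RNA gene BC055402 rose (0.46, 0.895 ± 0.204 against 0.388 ± 0.249). Rpl14-ps1, Rpl34-ps1 and Gm13456 were also called higher in AD at 5 mpi. Both contrasts use the same Ctrl libraries of 5 mpi, so they are not separate results for these genes. Of the lists, markers of thalamus and habenula, which border the hippocampus, were lower at 5 mpi (13 of 13 negative, mean -0.36; 0 over all genes and 5 adjusted over the list alone; fry adjusted p = 0.0312; adjusted p = 0.0687 with an estimated correlation). Unadjusted p-values under 0.05 numbered 1368, DESeq2 called 38 genes and edgeR 8. Leaving out single libraries gave 1 to 12 genes, and 12 without Ctrl library 2 of 5 mpi. Covariates gave 17 to 22 genes and only the compared groups 16.

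Age in Ctrl mice was compared across the cohorts, averaged over times, with 18 libraries at 12 months and 15 at 3 months. In total 4419 genes differed, 2131 higher and 2288 lower at 12 months (limma; edgeR 4337, DESeq2 4480). The immunoglobulin genes Igkv4-55 (1.99) and Ighm, the heavy chain of IgM (1.08; 96.1 ± 75.9 against 44.1 ± 44.0), rose, as did Spp1, which encodes osteopontin (0.91, SE 0.22). So did 6 genes of the meningeal fibroblast list, among them Slc6a13, a GABA transporter (0.93), Ogn, a matrix proteoglycan (0.87), Slc22a6 (0.86) and Ptgds, prostaglandin D synthase (0.86). Choroid plexus genes fell, with Ttr, which encodes transthyretin, at 1402 ± 1632 against 3734 ± 2160 (log2 fold change -1.95, SE 0.65, adjusted p = 0.0256), Tmem72 (-1.84), Aqp1, the water channel of this epithelium (-1.73), Folr1, a folate receptor (-1.58), and Cldn2, a tight junction claudin (-1.49). The neurogenesis genes Dcx, which encodes doublecortin (-0.33), and Igfbpl1 (-0.92) fell, the microglial genes Itgam (0.31) and Gpr34 (0.36) rose, and Hspd1, a mitochondrial chaperone, rose (0.28, SE 0.029, adjusted p = 1.08e-10). The mitochondrially encoded mt-Co3 fell (-0.69, SE 0.055; 27.0 ± 2.62 against 44.3 ± 5.40). Each cohort is 1 deposited table, so age cannot be told apart from any difference in collection or sequencing between the tables. Gm42418, a sign of ribosomal RNA carry-over, averaged 935, 752 and 970 in 12-month Ctrl libraries of 1, 3 and 5 mpi. In 3-month Ctrl libraries it averaged 1369, 1138 and 1216. Sex was unbalanced as well, with high Xist in 10 of 18 libraries at 12 months and 4 of 15 at 3 months. With a covariate for sex-linked genes 3868 genes were called, 3690 of them among the 4419.

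By list, 17 of 17 choroid plexus genes were lower over all genes and also adjusted over the list alone (mean -1.41; fry adjusted p = 0.0122; adjusted p = 0.613 with an estimated correlation). This difference lay in the same libraries as the lists that follow, and whether those lists depend on it was not tested. Meningeal fibroblast genes gave 6 of 16 higher on both counts, over all genes and adjusted over the list alone (mean 0.36; fry adjusted p = 0.2005; adjusted p = 0.831 with an estimated correlation). The score of that list averaged 5.10 at 12 months against 4.49 at 1 mpi, but 4.94 against 5.09 at 5 mpi. B and plasma cell genes gave 1 of 13 higher on both counts, over all genes and adjusted over the list alone (mean 0.34; fry adjusted p = 0.2005; adjusted p = 0.831 with an estimated correlation). Homeostatic microglia genes were higher in 9 of 16 over all genes and 11 adjusted over the list alone (fry adjusted p = 3.37e-04; adjusted p = 0.493 with an estimated correlation). Peripheral myeloid genes gave 3 of 14 higher and 8 adjusted over the list alone (fry adjusted p = 0.00699; adjusted p = 0.613 with an estimated correlation). Adult neurogenesis genes gave 8 lower and 1 higher of 13 over all genes and adjusted over the list alone (fry adjusted p = 6.29e-06; adjusted p = 0.351 with an estimated correlation). Chaperone genes gave 13 higher of 25 over all genes, and 14 higher and 1 lower adjusted over the list alone (fry adjusted p = 9.01e-04; adjusted p = 0.493 with an estimated correlation). Immediate early genes, induced by neuronal activity, were higher in 8 of 20 over all genes and 9 adjusted over the list alone, with Fos at 0.60 (fry adjusted p = 0.0245; adjusted p = 0.613 with an estimated correlation). Mitochondrially encoded genes gave 1 higher and 5 lower of 13 on both counts, over all genes and adjusted over the list alone (fry adjusted p = 4.24e-04; adjusted p = 0.613 with an estimated correlation). Myelin genes gave 9 lower of 20 on both counts, over all genes and adjusted over the list alone, with Mag at -0.30 (fry adjusted p = 0.0985; adjusted p = 0.831 with an estimated correlation). Some of these differences depended on time. The myelin score averaged 6.13 at 12 months against 6.41 at 1 mpi and 6.26 against 6.45 at 3 mpi, but 6.31 against 6.16 at 5 mpi. The adult neurogenesis score was 2.83 against 3.24 at 1 mpi but 2.65 against 2.68 at 5 mpi. The choroid plexus score was 4.30 against 5.72 at 1 mpi and 3.91 ± 1.49 against 4.32 ± 1.46 at 5 mpi.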

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

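The 3 tests on the glial lists, the test on low values in control libraries at 5 mpi and the 3 tests on the 3-month control comparison were chosen after their results were seen, as were the splits of single gene lists.

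In the 12-month cohort the glial lists were higher in AD libraries, with a mean log2 fold change of 0.25 (SE 0.0614) for disease-associated microglia genes. The tables argue against choroid plexus content as the whole cause, since the mean was 0.20 (SE 0.0563) with the choroid plexus score in the model. They also argue against a lower share of neurons that raises all other cells alike, since the list exceeded the endothelial list (0.05) by 0.20 (SE 0.0493). A lower share of neurons through more white matter is not covered by that comparison and stays open. The synapse list was lower, with a mean of -0.07. White matter content stays open: with the myelin score in the model the mean was 0.13 (SE 0.0623), over 2 SE but under 3 SE from 0, and the bound for excluding it was moved from 2 to 3 SE after these values were seen. In 100 splits of the libraries 31 called at least the 16 lists of the real groups (highest other 26), so chance is not excluded for the number of lists. A microglial response to AD extract is a hypothesis that these values do not tell apart from white matter content (0.13 with the myelin score), and counts of microglia and of myelin in tissue sections would be a test of it.

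At 5 mpi of the 12-month cohort 11 genes were higher in AD libraries, 10 of them processed pseudogenes, with a median log2 fold change of 0.42. Reads of the parent genes stay open: the 5 parents that the symbols name had a median of -0.051, which met the bound set beforehand, but that bound was wrong, since it leaves out 6 called genes and a changed share of stray reads would barely move a parent (for Vcp a log2 change of -0.0061 against an SE of 0.030). A shift of processed pseudogenes as a class stays open, with a median of 0.065 over 795 others (73.5% positive, against 0.036 over protein-coding genes of similar level), which lies between the bounds set beforehand. Low values in the 5 mpi control libraries alone stay open too: the genes differed by -0.38 between Ctrl libraries of 5 and 1 mpi and by 0.09 between AD libraries, which the first bound took as a sign of it, but by -0.23 between AD libraries of 3 and 1 mpi (11 of 11 lower, from -0.59 to -0.06), a test that was added after these values were seen. Of 100 splits 1, the real one, called as many (11, highest other 6). So many results were counted over splits that this does not exclude chance. An effect of AD extract at this time is untested among the open explanations.

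In 3-month controls 1836 genes differed between 5 and 1 mpi. Choroid plexus content is argued against as the whole cause, since 1348 of them stayed called with its score in the model, among 1993 called. The 2 Ctrl libraries of 1 mpi with high Inhba stay open: without both, 351 genes were called, 311 of them among the 1836. Time after injection, the age of the mice at collection and the session in which each time point was collected cannot be told apart here. Each would give the same direction in AD libraries of the same times, seen in 95.8% of the called genes (73.6% of all genes). In 12-month controls 37.7% of the 1824 tested changed in the same direction, so most of these genes changed in the opposite direction in the older cohort. The share over all genes was not counted for this comparison. Of 100 splits 1, the real one, called as many (highest other 301). The gap argues against chance, but 1 is the lowest value this count can take, so the splits do not exclude chance.

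Means of single lists were counted over the same 100 splits. At 12 months the real groups alone gave so large a mean for 11 of 39 lists: disease-associated microglia (highest other 0.16), homeostatic microglia (0.097), reactive astrocyte (0.16), complement (0.19), cytokines and NF-kB (0.099), myelin (0.14), oligodendrocyte precursor (0.059), ependymal (0.30), synapse (0.06), lysosome (0.061), and tau and Alzheimer risk (0.037). At 3 months, where limma called no gene (DESeq2 5), the same held for 1 of 39 lists, the mitochondrially encoded genes (0.10, highest other 0.092), and 2 splits gave so large a mean for glucocorticoid response genes (0.31, highest other 0.31). So many lists were looked at that 1 split in 100 for a single list does not exclude chance.

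Splits of the same libraries were also counted for the other limma results, 100 for each unless said otherwise. The gap was widest for age in controls (1 split; 4419, highest other 1), which argues against chance there, though 1 is the lowest value this count can take. Few splits gave as many genes for the 12-month AD mean (1 split; 2, highest other 1) or at its unadjusted p under 0.05 (2 splits; 3075, highest other 4019). The same held for the change of the AD effect from 1 to 5 mpi (2 splits; 1, highest other 150) and for 12-month controls over time (1 split; 5, highest other 1). So many results were counted this way that 1 or 2 splits in 100 do not exclude chance for these 4. Chance was also not excluded for 12-month AD at 1 mpi (6 splits; 1, highest other 83) or for the same-sign share between cohorts (9 splits; 55.9%, highest other 63.2%). The same holds for the 3-month lists (62 splits; 11, highest other 26) and the 3-month genes at an unadjusted p under 0.05 (39 splits; 790, highest other 4089). Where limma's count was 0, with the other tools' counts given above, each split gave at least as many. A count of 0 fixes that outcome in advance, so it tests nothing. The highest other count was 293 for the 3-month AD mean, 1548 and 1 at its 1 and 3 mpi, 59 for its change over time, 165 for 12-month AD at 3 mpi, and 3, 274, 0 and 4 for the difference between ages in the mean and at 1, 3 and 5 mpi, over 100 splits each, and 1 over the 56 splits of 3-month AD at 5 mpi. Some splits called many more genes than the real groups, such as 1548, 293, 274, 165 and 150. What those splits separated was not tested.

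Of 187 groups of values tested, 13 held a library apart from its group, where chance gives 9.35. In the 3-month cohort, AD library 3 of 1 mpi had Gfap at 1908 (next 927) and Serpina3n at 268.7 (next 142), and AD library 6 of that group had a depth of 65.9 M reads (next 50.6 M). At 3 mpi, AD library 4 had Cst7 at 1.09 (next 0.483), Clec7a at 4.20 (next 2.26) and Mapt at 444 (next 471). Ctrl library 4 of 3 mpi had Apoe at 1286 (next 1536) and Cd68 at 5.69 (next 8.18), and Ctrl library 2 had Mapt at 518 (next 475). In the 12-month cohort, App stood at 1890 in AD library 1 of 3 mpi (next 1761), Apoe at 1325 in AD library 1 of 5 mpi (next 1660), Cst7 at 2.24 in Ctrl library 2 of 5 mpi (next 0.878), and the myelin score at 6.07 in Ctrl library 6 of 5 mpi (next 6.28). Gm1821 differed between times in its AD effect, by 0.52 from 1 to 5 mpi of the 12-month cohort (limma adjusted p = 0.0444), above the Ctrl mean in 7 of 7 AD libraries at 5 mpi and 0 of 6 at 1 mpi.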

How the results depend on the processing

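The edgeR test, the pseudocount of 0.1, the choroid plexus and sex-gene covariates together, the myelin covariate, the 2 sets of libraries left out and the tables kept as deposited were chosen after seeing the data, and the other settings were planned. Of the counts and shares, 238 stayed within 1.5 times or within their spread under another setting, 78 moved and 1 turned its direction. Of the values of single genes and lists, 3411 kept direction and side of the threshold, 195 lost the call, 67 gained it and 31 changed sign. With single libraries left out, 395 counts and shares stayed and 100 moved, and 4228 single values stayed, 248 lost the call, 47 gained it and 39 changed sign. A list was not tested under its own score as covariate (choroid plexus, myelin). The age comparison in controls stayed within 1.5 times of its count of 4419 under each setting (3090 to 4732) and without any library (3832 to 4614), as did the called lists without any library (9 to 15 at 3 months, 14 to 21 at 12 months). Simulated 1.5-fold changes were recovered in 74% with 3 AD libraries at 5 mpi of the 3-month cohort and in 84% with 7 at 12 months. For the changes below the cause was not tested.

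With DESeq2 the count went from 0 to 5 for the 3-month AD mean (3 higher, 2 lower), 2, 1 and 7 at its 1, 3 and 5 mpi, and 3, 1 and 10 for the difference between ages in the mean and at 3 and 5 mpi. DESeq2 gave 163 for the 12-month AD mean, 42 and 27 at 1 and 5 mpi, 5 for 5 against 1 mpi and 38 for controls over time. The 12-month AD mean, 2 genes, gave 1 with upper-quartile scaling and 0 with no filter, robust spread, the choroid plexus covariate alone or with sex genes, the surrogate variable, the myelin covariate, or without 2 libraries with low Xist beside Y-linked genes. The single call at 1 mpi gave 0 with no filter, the stricter filter, only the compared groups, the choroid plexus covariate alone or with sex genes, the surrogate variable, the edgeR test, a pseudocount of 0.1, the myelin covariate, or without the low-Xist libraries. The single call for 5 against 1 mpi gave 0 with relative-log-expression scaling, no filter, only the compared groups, the same covariates and without the low-Xist libraries, 2 with upper-quartile scaling and 3 with the edgeR test. AD at 5 mpi of the 12-month cohort, 11 genes, gave 7 with no filter, 0 with only the compared groups and 21 (10 shared) without the low-Xist libraries, and at 3 mpi no filter gave 2. No filter and only the compared groups each gave 3 for 3-month AD at 5 mpi, and no filter gave 5 for the difference between ages at 5 mpi. Controls over time at 12 months, 5 genes, gave 1 with no filter, 9 with the stricter filter or robust spread, 16 with only the compared groups, 20 with the choroid plexus or the sex-gene covariate, 22 with both, 21 with the surrogate variable, 17 with the myelin covariate, 8 with the edgeR test and 11 with a pseudocount of 0.1. Controls over time at 3 months, 1836 genes, gave 895 (795 shared) with only the compared groups, which leaves fewer samples, and 880 (658 shared) without the 4 libraries of 1 mpi with the highest Inhba. The called lists, 11 at 3 months and 16 at 12 months, became 0 and 0 with an estimated correlation, 0 and 9 by fry, and 9 at 12 months with the myelin covariate. The same-sign share between cohorts, 55.9%, was 58.6% for genes with a mean log2 value of at least 3, 64.6% for genes with an unadjusted p under 0.05 at 12 months, 54.1% with upper-quartile scaling, 53.4% with no filter, 57.2% with the stricter filter, 59.0% with the choroid plexus covariate, 54.8% with sex genes, 58.6% with both, 53.5% with the myelin covariate and 49.95%, the other side of chance, with the surrogate variable.

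Single libraries decided several counts. The 12-month AD mean ran from 0 to 66. It was 0 without Ctrl 1, 2, 3 or 4 or AD 1, 3 or 6 of 1 mpi, Ctrl 1, 2 or 3 or AD 1, 4 or 6 of 3 mpi, or Ctrl 1, 6 or 7 or AD 2, 3, 4 or 5 of 5 mpi. It was 1 without Ctrl 6 of 3 mpi, Ctrl 3 of 5 mpi or AD 7 of 5 mpi, 10 and 45 without AD 4 and AD 2 of 1 mpi, 29, 19 and 39 without Ctrl 4, Ctrl 5 and AD 2 of 3 mpi, and 66 without AD 1 of 5 mpi. C3 was called in 17 and Pcsk6 in 14 of the 37 fits, with adjusted p-values from 0.00327 and 0.00742 to 0.0904. At 1 mpi the count ran from 0 (Ctrl 1, 2, 3, 4 or 5 or AD 2, 3, 5 or 6 left out) to 3 (AD 1). At 5 mpi it was 6 without Ctrl 4, AD 2 or AD 5, 7 without Ctrl 3, AD 1 or AD 4, and 23 without AD 6. The change from 1 to 5 mpi was 0 without Ctrl 3, 4 or 5 or AD 1, 3, 4, 5 or 6 of 1 mpi or Ctrl 1, 4, 5, 6 or 7 or AD 1, 2, 4 or 5 of 5 mpi, 2 without Ctrl 1 of 1 mpi or AD 3 or AD 6 of 5 mpi, and 3 without AD 7 of 5 mpi. Controls over time at 12 months gave 1 without Ctrl 3 of 1 mpi or Ctrl 1 or 3 of 5 mpi, 2 without Ctrl 1, 2, 4 or 5 of 1 mpi or Ctrl 5 of 5 mpi, 3 without Ctrl 4 and 12 without Ctrl 2 of 5 mpi. In the 3-month cohort controls over time ran from 933 to 1944 (Ctrl 5 of 5 mpi 933, Ctrl 4 1094, Ctrl 3 1153, Ctrl 3 of 1 mpi 975, Ctrl 1 997). Without Ctrl 2 of 1 mpi, AD at that time gave 2 and its difference between ages 3, and without Ctrl 1 of 5 mpi, AD at that time gave 3, each 0 otherwise. The same-sign share ran from 51.3% without AD 2 of 5 mpi to 58.1% without AD 3 of 1 mpi, both of 3 months. It left its interval over genes, which is not a spread between libraries, in 15 of 66 fits.

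The genes among the log2 values that changed sign were uncalled. In the 3-month mean, App gave 0.0026 with the choroid plexus covariate, 0.0035 with sex genes, 0.0059 with both and -0.016 to 0.013 without single libraries. Cst7 gave -0.0082 with a pseudocount of 0.1, and the surrogate variable gave -0.0066 for Apoe, -0.024 for Trem2, -0.047 for Cd68, -0.018 for disease-associated microglia, -0.0039 for myelin and -0.0083 for complement genes. Without the 4 libraries with the highest Inhba the synapse list gave -7.3e-04. Without single libraries Gfap ran from -0.10 to 0.048, synapse from -0.0097 to 0.022, disease-associated microglia from -0.016 to 0.078, complement from -0.018 to 0.15 and reactive astrocyte genes from -0.023 to 0.12. At 1 mpi, Gfap gave -0.0071 with upper-quartile scaling, -0.0013 with DESeq2, -1.3e-04 with the edgeR test, -0.038 with choroid plexus, -0.010 with sex genes, -0.030 with both and -0.20 to 0.25 without single libraries, and Serpina3n -0.026, -0.012 with both and -0.20 to 0.20. At 3 mpi the surrogate variable gave -0.052 for Apoe, -0.0090 for Itgax and -0.14 for Cd68, and without single libraries Cd68 ran from -0.060 to 0.085, Cst7 from -0.13 to 0.022 and Aif1 from -0.0071 to 0.11. At 5 mpi the choroid plexus covariate alone and with sex genes gave 0.046 and 0.065 for Apoe, 0.028 and 0.038 for Trem2, and both gave -0.014 for Serpina3n, while without single libraries Trem2 ran from -0.11 to 0.063, Aif1 from -0.026 to 0.050, C4b from -0.12 to 0.28 and App from -0.024 to 0.065. In the 12-month cohort the choroid plexus list gave -0.096 in the mean with the surrogate variable, Cd68 at 1 mpi -0.042 with the myelin covariate, and Mapt at 3 mpi -0.0064 with upper-quartile scaling and -0.015 to 0.035 without single libraries.

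With the replicate number as a block, the 12-month AD mean gave 1 gene in place of 2, AD at 1 mpi and the change from 1 to 5 mpi 0 in place of 1, controls over time 1 in place of 5 at 12 months and 1943 (1690 shared) in place of 1836 at 3 months, and the synapse list of the 3-month mean -0.0066. No other count moved by over 1.5 times. Libraries of the same number had a median correlation of deviations of -0.02 at 3 months and -0.04 at 12 months, and 3 of 29 and 8 of 37 lay closest to their own number, so the numbers do not pair the libraries.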

Other observations

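The values here were picked after they were seen, and no test was run on them beyond those given above. The clock genes Dbp, Nr1d1 and Per2 differed in mean between time points in some groups. Per2 averaged 28.7 ± 6.05 (n = 6), 43.1 ± 4.42 (n = 5) and 34.8 ± 6.41 (n = 3) in 3-month AD libraries of 1, 3 and 5 mpi, and 28.6 ± 3.64 (n = 5), 32.0 ± 6.78 (n = 6) and 31.6 ± 3.25 (n = 7) in 12-month Ctrl libraries. In the 3-month cohort Dbp, a clock output transcription factor, averaged 19.9 ± 8.62 (n = 5), 58.6 ± 7.58 (n = 5) and 52.5 ± 4.57 (n = 5) in Ctrl libraries of 1, 3 and 5 mpi, and 21.4 ± 3.70 (n = 6), 54.9 ± 6.96 (n = 5) and 49.2 ± 10.3 (n = 3) in AD libraries. In the 12-month cohort the Dbp means at 1 and 5 mpi both lay below that at 3 mpi: 32.5 ± 7.21 (n = 5), 45.8 ± 1.77 (n = 6) and 26.5 ± 1.94 (n = 7) in Ctrl and 27.2 ± 3.46 (n = 6), 51.1 ± 3.65 (n = 6) and 27.1 ± 3.49 (n = 7) in AD libraries. Nr1d1, which encodes REV-ERB alpha, was also highest at 3 mpi in 12-month libraries, at 55.9, 70.1 and 50.3 in Ctrl and 52.9, 76.2 and 55.3 in AD. In the 3-month cohort Nr1d1 was instead highest at 5 mpi, at 46.8, 73.5 and 82.9 in Ctrl and 54.6, 65.9 and 76.9 in AD.

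Transcripts of structures outside the hippocampus varied widely between libraries of a group. Ttr of the choroid plexus ran from 25.4 to 9329 over the 66 libraries and averaged 1757 ± 1710 (n = 5) in Ctrl and 289 ± 368 (n = 3) in AD libraries at 5 mpi of the 3-month cohort. The pituitary hormone genes Prl, Gh and Pomc were detected as well: in AD library 3 of 3 mpi of the 3-month cohort, Prl stood at 264.6, Gh at 78.7 and Pomc at 72.0, the highest of the 66 libraries for each. That library had high Xist (698), and a dependence of these hormone genes on sex was not tested. Tcf7l2, a thalamic transcription factor gene, stood at 51.0 in AD library 1 of 1 mpi and 49.8 in Ctrl library 4 of 5 mpi of the 3-month cohort, and at 18.9 or less in the others. Inhba stood at 95.1 and 84.1 in Ctrl libraries 1 and 3 and at 53.5 and 38.9 in AD libraries 3 and 6 of 1 mpi of the 3-month cohort, and at 23.1 or less in the others.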
